A study of Mus musculus with 13 samples.

How the data were processed

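Gene expression was measured by sequencing polyA RNA from tumors of 13 NSG mice carrying ID8 cells. Per the labels' protocols, tumors were collected at endpoint, snap frozen and crushed before RNA extraction, and libraries and sequencing were made by core and commercial facilities. Per the submitters' processing notes, Trim Galore 0.5.0, STAR 2.6.1d, featureCounts, Subread 1.6.4 and the GRCm38 genome were used; their settings, the annotation release, the use of strand and the treatment of reads with several alignments are not given in the sources used here. Each library came as a deposited table of raw counts per Ensembl gene, whole numbers with no normalization by the authors, with the gene length per the file headers. Without strand, reads of a gene and of an overlapping or antisense gene, such as Gm13703, Gm47766 or Gm5144 (which overlaps Npr3), cannot be told apart, and genes with near-identical copies, such as ribosomal protein and mitochondrially encoded genes with their pseudogenes, are uncertain for the same reason.

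All 55471 gene identifiers were matched to GENCODE release M21, and 55230 were found there; the 241 others took at most 0.0047% of the counts of a library and stayed in the tests without a symbol. Library totals were 33131908 to 48636526, so that 3 counts, the limit that a count of 0 allows, correspond to 0.0617 to 0.0905 CPM of the unscaled totals. The other CPM values are on TMM-scaled sizes, where the same counts give somewhat different values. This limit covers counting error only. No pair of libraries of a group had more than 4.03% of expressed genes at equal counts, and none was treated as a duplicate. The most alike pair of all crossed the groups. Water and cisplatin library 4 and water and placebo library 2 had 4.09% at equal counts and a correlation of log CPM of 0.979. Groups and replicate numbers came from the labels, which give 1 mouse per library, so p-values of single genes measure the spread between mice. Camera p-values at a preset correlation compare the genes of a list with the other genes. They do not measure the spread of the list between mice.

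The main test was edgeR's quasi-likelihood F test (edgeR 4.0.16, limma 3.58.1, R 4.3.3) on the counts, with TMM factors, filterByExpr by group and 1 fit of 4 group means over all 13 libraries, so that groups of 2 to 4 mice shared an estimate of the spread. Adjusted p-values are Benjamini-Hochberg within a contrast, with a threshold of 0.05. The 7 contrasts were cisplatin against placebo with water and with antibiotics, antibiotics against water with cisplatin and with placebo, their interaction, and both effects averaged over the other factor. The biological coefficient of variation was 0.588. Values are given as CPM on TMM-scaled library sizes, as mean ± SD over mice, and log2 fold changes as estimate ± SE, with the SE derived from the F statistic.

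Before the data were examined, 33 gene lists with 625 entries (response pathways, cell types and quality markers), the contrasts, most alternatives and the rule for named genes were fixed. Lists with at least 5 tested genes were tested with limma's camera at a preset correlation of 0.01, adjusted over the 32 such lists within a contrast, and again with an estimated correlation and with fry. The rule named up to 8 genes at each end among those past the threshold, 3 members per list past it, the 10 genes with the smallest p where fewer than 5 passed, and 12 genes in the 4 pairwise contrasts whatever the test said. Since no gene passed, only the last 2 parts applied. Members of a list that the text gives as examples beyond these were chosen after their values were seen. Listed symbols were matched to current ones for 2 genes, and Aldoa and Ddit3, which match 2 identifiers each, were left out. Marker lists of 5 further tissues and a set of 5 ovarian surface markers were chosen once the data had been seen. They are used for levels per library, for the correlation of markers within tissues and for the relations across libraries.

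Alternatives were RLE factors, no filter, a filter of at least 1 CPM in 4 libraries, a robust dispersion, DESeq2 1.42.0, limma voom, the replicate number as a block, a letter carried by the names of 6 of the 13 libraries as a factor, fits to the 2 groups compared, and leaving out each library. Added after seeing the data were leaving out the 2 libraries highest in skeletal muscle, leaving out mitochondrially encoded genes, the adipocyte level as a covariate, and an exact permutation of library means (SciPy 1.17.1, Python 3.11.15). The meaning of the letter is not given in the labels; the 6 libraries with it had totals of 33131908 to 38031155 and the 7 without it 38567356 to 48636526.

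The tests were tested on simulated data drawn from the means, library sizes and dispersions of the real genes, with 200 genes changed. For cisplatin against placebo in water mice, 51% of genes changed 4-fold and 93% of those changed 16-fold were recovered among 18250 genes, with 7 false calls. The values were 45% and 89% for cisplatin in antibiotic mice among 18187 genes, 71% and 91% for antibiotics in cisplatin mice among 18256 genes, and 36% and 85% for antibiotics in placebo mice among 18173 genes, with 10, 5 and 4 false calls. A list changed 2-fold was called by camera in each of the 4 simulations and 0 of the other 31 lists were. Simulated genes vary independently, which the real genes do not. Of the unchanged simulated genes 4.7 to 4.79% had an unadjusted p under 0.05 in edgeR. In the same 4 comparisons of the real data 0.522 to 19% of genes did. The recovery in the real data may therefore differ from that in the simulations.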

Results

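RNA was measured in tumors from 13 NSG mice, an immunodeficient strain without mature T, B and NK cells, that carried ID8 tumors. ID8 is a mouse ovarian surface epithelial cell line used as a model of epithelial ovarian cancer. The mice formed a 2 by 2 layout of antibiotics or plain water and of cisplatin, a DNA-crosslinking platinum drug, or placebo. There were 3 mice with water and placebo, 4 with water and cisplatin, 2 with antibiotics and placebo, and 4 with antibiotics and cisplatin, each giving 1 polyA RNA library from a tumor taken at endpoint. Library totals ran from 33131908 to 48636526 counted reads, and 19149 genes were tested. The title of the series states the question as whether disruption of the gut microbiota lowers the response of the tumors to cisplatin.

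The libraries held markers of several host tissues, in amounts that differed widely between mice of 1 group. Skeletal muscle myosin Myh4 reached 7710 CPM (counts relative to the TMM-scaled library size) in antibiotics and cisplatin library 1. It was at 2330 CPM in water and placebo library 3. In water and cisplatin libraries 2 and 3 it was at 0.0175 and 0.0181 CPM. Smooth muscle myosin Myh11 reached 21100 CPM in water and placebo library 1 and 21.2 CPM in antibiotics and cisplatin library 2. The bladder lining gene Upk2 ran from 0 to 3000 CPM, and the oviduct glycoprotein Ovgp1 from 0.138 to 1390 CPM. Markers of uterine epithelium ran from -1.14 to 6.92 (mean log2 of CPM + 0.1). Oocyte and granulosa cell genes marked other libraries, with Padi6 at 49.3 CPM in water and cisplatin library 3 and 48.7 CPM in antibiotics and placebo library 1. The milk protein gene Csn3 reached 260 CPM in water and placebo library 3. Fat was present in all 13 libraries: adiponectin (Adipoq) ran from 274 to 4880 CPM. The ovarian surface and mesothelial gene Wt1 ran from 7.39 CPM in water and placebo library 3 to 978 CPM in antibiotics and cisplatin library 2. Along the first principal component of the 1000 most variable genes, which held 51% of their variance, oviduct and granulosa genes such as Ovgp1 and Hsd3b1 lay at one end and muscle genes such as Myh4 and Ckm at the other. Mitochondrially encoded genes took 5.47 to 30.5% of the counts of a library.

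**Figure D1:**
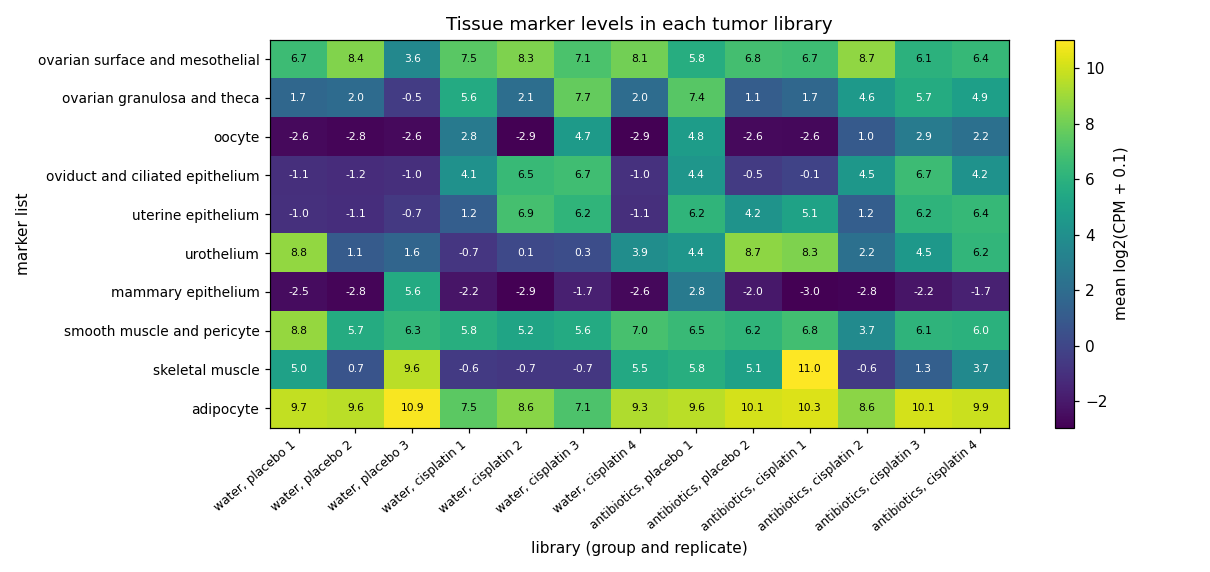
Level of 10 marker lists (rows, mean log2 of CPM + 0.1 over the list, by color and printed value) in each of the 13 tumor libraries (columns, by group and replicate). Skeletal muscle, urothelial, oviduct and oocyte markers differ widely between libraries of 1 group, while the adipocyte list lies between 7.1 and 10.9 in all 13.

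Cisplatin against placebo in water mice asks what the drug leaves in tumors of mice with an intact microbiota. On average, fat markers and mitochondrially encoded transcripts were lower in the 4 cisplatin tumors than in the 3 placebo tumors, and cell cycle and immediate early transcripts were higher. Of these only the fat and immediate early levels of the groups did not overlap, and the calls of all 4 lists were lost at adjusted p = 0.643 with an estimated correlation. Water and placebo library 2, with an ovarian surface marker level of 8.36 against 7.07 to 8.32 in the cisplatin libraries and 6.65 and 3.57 in the other placebo libraries, had an immediate early level of 6.81 log2 CPM, next to the cisplatin range of 6.87 to 7.99. The adipocyte list averaged 8.13 ± 1.01 log2 CPM (SD, n = 4) with cisplatin, 7.12 to 9.34 in single libraries, and 10.08 ± 0.72 (SD, n = 3) with placebo, 9.61 to 10.92. Of its 16 genes, 15 had lower estimates, with a median log2 fold change of -1.83. Among them were the hormone leptin (Lep, log2 fold change -4.24 ± 0.86, SE), the lipid droplet protein Plin4 (-2.01 ± 0.51), adiponectin (Adipoq, -2.08 ± 0.57) and the adipocyte regulator Pparg (-1.55 ± 0.43). The mitochondrial level was 10.27 and 9.61 log2 CPM in water and placebo libraries 1 and 3, which were rich in smooth and skeletal muscle markers, and 8.02 in library 2, within the cisplatin range of 7.18 to 8.74. All 13 mitochondrially encoded genes had lower estimates, with a median of -1.81; mt-Nd5, a subunit of respiratory complex I, stood at -2.29 ± 0.60.

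No single gene passed in this comparison: edgeR's quasi-likelihood test called 0 of 19149 genes, with 3640 genes at an unadjusted p under 0.05 (1572 higher, 2068 lower) where 957 would be expected. Limma voom called 0, and DESeq2 called 1399 (587 higher, 812 lower). Adjusted over the list alone, 12 of the 16 adipocyte genes and 10 of the 13 mitochondrial genes passed, all of them lower. Over all genes edgeR called 0 of either list, and DESeq2 called 10 of the 16 and 6 of the 13, all lower. The 10 genes with the smallest p, none of them called, all had lower estimates. They included the transcription cofactor Lmo4 (ENSMUSG00000028266, GRCm38 chromosome 3, 144188530 to 144205220), at 123 ± 10.9 CPM (SD, n = 4) against 250 ± 29.5 CPM (SD, n = 3), with an edgeR adjusted p of 0.21. The endolysosomal cation channel Tpcn1 (ENSMUSG00000032741, chromosome 5, 120534153 to 120588673) stood at 125 ± 6.2 against 257 ± 43.8 CPM, and the glycolytic regulator Pfkfb3 at 61.6 ± 29.9 against 288 ± 179 CPM. The others were Lep, Ric3, Ttc28, Dusp3, Npr3, Atg7 and the antisense transcript Gm13703, with log2 fold changes from -4.24 (Lep) to -1.07 (Ttc28) and the same adjusted p of 0.21.

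Tests of the fixed lists with limma's camera and a preset correlation called 15 of 32 lists. Higher were proliferation (30 of 32 genes, median 1.25, adjusted p = 1.81e-08), immediate early genes (16 of 16, median 1.64, adjusted p = 4.27e-07), NF-kB and inflammatory mediators (21 of 23, median 0.77), stem cell markers (21 of 24, median 0.74), DNA repair (28 of 39, median 0.43) and ovarian granulosa and theca genes (12 of 12, median 3.90). The last came from water and cisplatin libraries 1 and 3 (5.57 and 7.72 log2 CPM), which also carried oocyte markers. Libraries 2 and 4 (1.82 and 1.73) were near the placebo libraries (-0.76 to 1.67). Oviduct markers were at 4.13, 6.45, 6.74 and -0.97 (mean log2 of CPM + 0.1) with cisplatin and at -1.18 to -1.04 with placebo. Uterine markers were at 1.25, 6.92, 6.22 and -1.06 against -1.14 to -0.65. Whether such tissue brought the higher stem cell markers was not tested. Each of the 6 higher lists lost its call when the correlation was estimated from the data: adjusted p = 0.643 with an estimated correlation, and 0.655 for DNA repair. Lower were the adipocyte (adjusted p = 1.42e-13), mitochondrial (adjusted p = 1.66e-08), MHC class I (13 of 13 genes, median -0.79), smooth muscle (15 of 15, median -1.38), skeletal muscle (15 of 15, median -4.75), fibroblast (20 of 20, median -0.55), endothelial (19 of 20, median -0.61), angiogenic factor (13 of 18, median -0.60) and ribosomal protein (27 of 30, median -0.34) lists. These calls were lost as well, at adjusted p = 0.643 to 0.743 with an estimated correlation. Only 8 of the 15 lists kept call and direction without each single library: the smooth muscle median was -0.20 without water and placebo library 1 and the skeletal muscle median -0.28 without library 3, neither called. The ribosomal median was 0.02 without water and placebo library 1 and the endothelial median -0.11 without library 3, again not called. The DNA repair, angiogenic factor and fibroblast lists also lost their calls without 1 library. In edgeR 0 genes of the proliferation, immediate early, NF-kB, stem cell, DNA repair, MHC class I and endothelial lists passed adjusted over the list alone or over all genes. DESeq2 called 1 immediate early and 1 NF-kB gene higher, 1 DNA repair and 1 MHC class I gene lower, and 0 in the other 3. In the rest of the called lists it called 4 granulosa and theca genes higher, 3 smooth muscle, 1 angiogenic factor and 1 fibroblast gene lower, and 0 ribosomal and skeletal muscle genes. With the adipocyte level as a covariate 9 of the 15 called lists had the opposite direction, but as the adipocyte levels of the 2 groups do not overlap, that fit extrapolates and cannot decide. The adipocyte list was among the 15, and its own level was the covariate, so its outcome there was set in advance. Mki67, a marker of dividing cells, stood at 91.8 ± 56.5 against 36.1 ± 37.8 CPM (log2 fold change 1.35 ± 0.83) and Brca1 at 7.13 ± 3.68 against 2.43 ± 2.14 CPM (1.54 ± 0.89). Mki67 was at 176 CPM in water and cisplatin library 3, the highest of its group in granulosa and theca genes, and at 54.4 to 72 CPM in the others.

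The p53 targets did not move as a group: 13 of 24 had higher and 11 lower estimates (median 0.17, camera adjusted p = 0.953), and in edgeR 0 passed adjusted over the list alone or over all genes. DESeq2 called 1 of them higher and 1 lower. Tumors were taken at endpoint, and the time since the last cisplatin dose was not found in the labels used here. A p53 response at another time is therefore not excluded. The cell cycle inhibitor Cdkn1a stood at 70.6 ± 15.6 against 165 ± 130 CPM (log2 fold change -1.23 ± 0.45, edgeR adjusted p = 0.215), the p53 antagonist Mdm2 at 27.4 ± 7.01 against 19.3 ± 5.54 CPM, and the stress cytokine Gdf15 had an estimate of 2.25 ± 0.71. The other genes named in advance were likewise not called: Ercc1, a nucleotide excision repair endonuclease subunit (-0.55 ± 0.32), Pecam1 of the endothelium (-0.43 ± 0.56), Vegfa (0.75 ± 0.62), Aldh1a1 (0.49 ± 0.55), Prom1 (2.93 ± 1.21), Cd44 (0.47 ± 0.40), Isg15 (-0.46 ± 0.25) and Msln (0.21 ± 0.71). Without water and placebo library 2 edgeR called 102 genes, and the number at an unadjusted p under 0.05 ran from 1635, without water and placebo library 3, to 5309, without library 2. An exact two-sided permutation test of library means passed no list, at a smallest p of 0.0571. This is also the smallest that the test, as computed, can give for 3 against 4 mice.

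**Figure D2:**
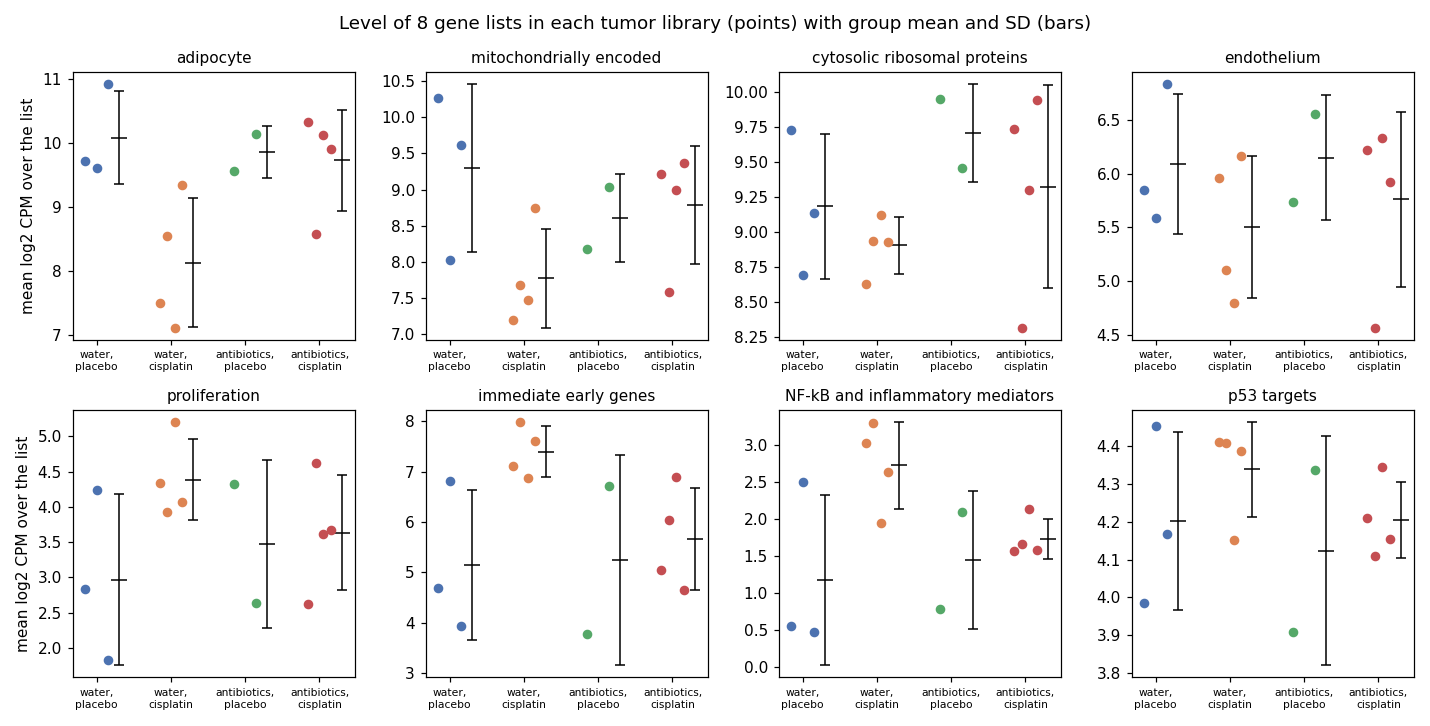
Level of 8 gene lists (mean log2 CPM over the list, vertical axis, own scale per panel) in each tumor library (points) by group (horizontal axis), with the group mean and SD as bars. In the adipocyte panel the 4 water and cisplatin libraries, 7.12 to 9.34, lie below the 3 water and placebo libraries, 9.61 to 10.92, while the p53 target panel spans only 3.91 to 4.45.

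Cisplatin against placebo in antibiotic mice asks the same of mice whose microbiota was disrupted. In these tumors the adipocyte list was at 9.73 ± 0.79 log2 CPM with cisplatin (SD, n = 4) and 9.86 ± 0.41 with placebo (SD, n = 2). Its median log2 fold change, 0.02, and its mean, -0.01, differed in sign (camera adjusted p = 0.757). The proliferation list was at 3.63 ± 0.82 and 3.48 ± 1.19. Hypoxia and glycolysis genes had higher estimates in 20 of 23 cases (median log2 fold change 0.30). Among them were the pyruvate dehydrogenase kinase Pdk1 (0.88 ± 0.46, SE) and hexokinase Hk2 (0.75 ± 0.40). All 30 ribosomal protein genes (median -0.28), 13 of 15 smooth muscle genes (median -0.49), 11 of 13 MHC class I genes (median -0.26) and 16 of 20 endothelial genes (median -0.25) had lower estimates. Camera with a preset correlation called these 5 lists (adjusted p from 3.54e-05 for ribosomal proteins to 0.0243 for endothelium), and all 5 calls were lost at adjusted p = 0.927 with an estimated correlation. Of the 5, 0 kept call and direction without each single library. Without antibiotics and cisplatin library 2 none was called, with medians of -0.03 for ribosomal proteins, -0.11 for smooth muscle, -0.09 for MHC class I, -0.02 for endothelium and 0.02 for hypoxia. In none of the 5 lists did a gene pass in edgeR, adjusted over the list alone or over all genes, or in DESeq2.

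EdgeR called 0 genes between these groups, with 100 at an unadjusted p under 0.05 where 957 would be expected (98 without antibiotics and cisplatin library 2). DESeq2 and limma voom also called 0. The 2 placebo libraries were unlike each other, with granulosa and theca levels of 7.39 and 0.87 log2 CPM. Their oviduct marker levels were 4.38 and -0.53 (mean log2 of CPM + 0.1). With fewer genes under that p than expected, the 0 calls do not show that cisplatin had no effect here. The interferon-induced membrane protein Bst2 (ENSMUSG00000046718, GRCm38 chromosome 8, 71534255 to 71537456) was among the 10 genes with the smallest p, at 68.1 ± 19.1 against 131 ± 7.4 CPM (edgeR adjusted p = 1). So were the linker histone gene Hist1h1a (0.129 ± 0.0607 against 0.707 ± 0.252 CPM) and Fam214a (29.9 ± 5.15 against 20.2 ± 1.04 CPM). Pcdhgc4, Map6d1 and Gm4129 were also on this list, all at means of 1.53 CPM or less. Gm44969, Tm4sf4, Gm47766 and AC148174.1 had no count in either placebo library and means of 0.185 to 0.268 CPM with cisplatin. In the placebo libraries 3 counts correspond to 0.0778 and 0.0789 CPM of the unscaled totals, while the means are on TMM-scaled sizes. Of the p53 targets, 16 of 24 had higher estimates (median 0.08, camera adjusted p = 0.504); Cdkn1a stood at 106 ± 41.4 against 120 ± 0.92 CPM and Mdm2 at 19.3 ± 4.73 against 16.9 ± 3.19 CPM. Mki67 (log2 fold change 0.69 ± 0.93), Brca1 (0.74 ± 0.99), Ercc1 (-0.16 ± 0.37), Pecam1 (-0.25 ± 0.63), Vegfa (0.70 ± 0.71), Aldh1a1 (0.57 ± 0.64), Prom1 (-0.15 ± 1.21), Cd44 (0.65 ± 0.46), Isg15 (-0.38 ± 0.28) and Msln (0.38 ± 0.81) were not called. The number of lists called ran from 3, without antibiotics and cisplatin library 2, to 12, without antibiotics and placebo library 2, and was 9 without antibiotics and placebo library 1 or without antibiotics and cisplatin library 1. The MHC class I and endothelial lists changed direction without antibiotics and placebo library 2, and the medians of ribosomal proteins (0.06) and smooth muscle (0.10) turned without antibiotics and placebo library 1.

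Antibiotics against water in cisplatin mice compares the treated tumors with and without a disrupted microbiota, and includes any effect the antibiotics have without cisplatin. On average the antibiotic tumors were higher in fat markers, ribosomal protein and mitochondrial transcripts, and lower in immediate early, inflammatory and cell cycle transcripts. The libraries of the groups overlapped in each of these lists, and the list calls were lost at adjusted p = 0.512 to 0.722 with an estimated correlation. All 16 adipocyte genes had higher estimates (median log2 fold change 1.42), with Lep at 2.70 ± 0.78 (SE), Adipoq at 1.52 ± 0.54 and the triglyceride lipase Pnpla2 at 1.69 ± 0.59. All 16 immediate early genes had lower estimates (median -1.35), including Egr2 (-2.38 ± 0.69) and Atf3 (-1.87 ± 0.94). So had 19 of 23 NF-kB and inflammatory mediators (median -1.12), among them the cytokines Il1a (-2.38 ± 0.95) and Tnf (-2.04 ± 0.93) and the monocyte chemoattractant Ccl2 (-1.44 ± 0.60). All 30 ribosomal protein genes (median 0.52) and all 13 mitochondrial genes (median 1.00) had higher estimates. The adipocyte level was 9.73 ± 0.79 log2 CPM with antibiotics and 8.13 ± 1.01 with water (SD, n = 4 each), and the ranges, 8.58 to 10.32 and 7.12 to 9.34, overlapped. The 4 water and cisplatin libraries are the same as in the comparison with placebo above, so the 2 comparisons share their chance values with opposite sign.

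Adjusted over the list alone, 11 of the 16 adipocyte genes and 1 of the 13 mitochondrial genes (mt-Co3) passed, all higher, and 0 passed over all genes; in the immediate early, NF-kB, proliferation and ribosomal lists 0 passed by either in edgeR. DESeq2 called 0 members of these 6 lists. Camera with a preset correlation called 12 lists: the adipocyte (adjusted p = 2.81e-17), ribosomal, mitochondrial, skeletal muscle, MHC class I and platinum transport and metallothionein lists were higher, and the immediate early (adjusted p = 3.72e-12), NF-kB, proliferation, stem cell, MHC class II and DNA repair lists were lower. All 12 calls were lost with an estimated correlation, and 6 kept call and direction without each single library. The skeletal muscle result rested on antibiotics and cisplatin library 1, without which its median was -0.74 and not called. With the adipocyte level as a covariate, 6 of the 12 had the opposite direction, 4 of them with a call: proliferation (median 0.54, adjusted p = 3.11e-07), DNA repair (0.17), MHC class I (-0.34) and skeletal muscle (-1.29). Calls in that fit came from camera with the preset correlation only. The adipocyte list was among the 12, and as its own level was the covariate, its outcome was set in advance. The immediate early (median -1.38), NF-kB (-1.05) and MHC class II (-0.20) lists kept direction and call in that fit, although the MHC class II list had lost its call in the fits without antibiotics and cisplatin library 3 or 4 or water and cisplatin library 1 or 4. In the platinum transport list 10 of 15 genes had higher estimates (median 0.62), led by the organic cation transporter Slc22a3 (1.54 ± 0.45), and 0 passed by either adjustment. The p53 targets gave a median of -0.16 (camera adjusted p = 0.391) and type I interferon response genes a median of -0.01 (adjusted p = 0.86).

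EdgeR called 0 genes, with 1205 at an unadjusted p under 0.05 (991 higher, 214 lower), limma voom called 0 and DESeq2 called 2. The smallest p was that of the glucocorticoid-responsive transcription factor Klf15 (ENSMUSG00000030087, GRCm38 chromosome 6, 90462576 to 90475238), with a log2 fold change of 1.52 ± 0.31 (edgeR adjusted p = 0.759). Another glucocorticoid-induced gene, Tsc22d3, stood at 64.8 ± 25.3 against 26.1 ± 2.21 CPM, the respiratory complex I subunit Ndufa1 at 156 ± 40.6 against 71.8 ± 4.5 CPM, and Pfkfb3 at 188 ± 53.4 against 61.6 ± 29.9 CPM. Olfm4, Lrrc4c, Fam213b and the transcripts Gm37716, Gm5144 and Gm13703 complete the 10 genes with the smallest p, all with higher estimates and an adjusted p of 0.759. The number at an unadjusted p under 0.05 ran from 508, without antibiotics and cisplatin library 1, to 4764, without antibiotics and cisplatin library 2. Genes named in advance were not called: Cdkn1a (0.58 ± 0.42), Mdm2 (-0.51 ± 0.25), Mki67 (-0.90 ± 0.74), Brca1 (-0.88 ± 0.79), Ercc1 (0.44 ± 0.30), Pecam1 (0.06 ± 0.52), Vegfa (-0.47 ± 0.56), Aldh1a1 (-0.47 ± 0.51), Prom1 (-0.97 ± 1.00), Cd44 (-0.57 ± 0.37), Isg15 (0.21 ± 0.23) and Msln (-0.41 ± 0.66).

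Antibiotics against water in placebo mice, 2 against 3 tumors, asks what the antibiotics alone do. Ovarian granulosa and theca genes had higher estimates in 11 of 12 cases (median log2 fold change 4.72), among them the steroidogenic enzyme Cyp17a1 (5.94 ± 1.98, SE) and the ovarian transcription factor Foxl2 (4.95 ± 1.81). In single libraries this list was at 7.39 and 0.87 log2 CPM with antibiotics and between -0.76 and 1.67 with water. The difference came from antibiotics and placebo library 1, and without it the median of this ovarian granulosa and theca list was -0.77. Ribosomal protein genes had higher estimates in 30 of 30 cases (median 0.49), and fibroblast genes in 19 of 20 cases (median -0.71), MHC class II genes in 14 of 14 (median -0.81) and mitochondrial genes in 13 of 13 (median -0.87) had lower ones. Camera with a preset correlation called these 5 lists and the hypoxia, smooth muscle and EMT regulator lists, which were lower (adjusted p from 2.23e-05 for fibroblasts to 0.0214 for EMT regulators). Of the 8 lists 3 kept call and direction without each single library. The ribosomal median was 0.13 without antibiotics and placebo library 1, the mitochondrial median was -0.21 without water and placebo library 1, and neither was called; the EMT regulator list lost its call as well. The smooth muscle median turned to 0.42 without water and placebo library 1, which had the highest Myh11. All 8 calls were lost at adjusted p = 0.554 to 0.783 with an estimated correlation. In edgeR no member of the 8 lists passed adjusted over the list alone or over all genes, and DESeq2 called 3 of the 12 granulosa and theca genes higher.

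EdgeR called 0 genes here, with 1023 at an unadjusted p under 0.05 (797 higher, 226 lower; 497 to 1243 without 1 library), limma voom called 0 and DESeq2 called 77 (75 higher, 2 lower). Among the 10 genes with the smallest p were the transcription factors Sall1 (16.7 ± 2.11 against 0.588 ± 0.377 CPM, edgeR adjusted p = 0.892; ENSMUSG00000031665, GRCm38 chromosome 8, 89027235 to 89044162) and Pax2 (14.4 ± 0.507 against 0.361 ± 0.227 CPM), Plekhs1 (101 ± 44.3 against 0.315 ± 0.232 CPM), Vwa2 (18.7 ± 14.1 against 1.36 ± 0.732 CPM) and Col6a4 (37.5 ± 42.2 against 1.33 ± 1.29 CPM). In the same libraries the oviduct and ciliated epithelium markers stood at 4.38 and -0.53 (mean log2 of CPM + 0.1) with antibiotics and from -1.18 to -1.04 with water, and the uterine epithelium markers at 6.22 and 4.23 with antibiotics and from -1.14 to -0.65 with water. A2m, Nkx2-3, Csf3, Gm47766 and Lmo4 were also among the 10, with Lmo4 at 143 ± 5.14 against 250 ± 29.5 CPM. Genes named in advance were not called: Cdkn1a (-0.46 ± 0.55), Mdm2 (-0.19 ± 0.33), Mki67 (-0.24 ± 0.96), Brca1 (-0.09 ± 1.02), Ercc1 (0.05 ± 0.39), Pecam1 (-0.12 ± 0.67), Vegfa (-0.42 ± 0.73), Aldh1a1 (-0.55 ± 0.67), Prom1 (2.12 ± 1.29), Cd44 (-0.76 ± 0.49), Isg15 (0.13 ± 0.30) and Msln (-0.58 ± 0.86). The number of lists called was 15 without water and placebo library 2 and 19 without antibiotics and placebo library 2.

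The interaction asks whether cisplatin acted differently with and without antibiotics. Adipocyte genes (16 of 16, median difference of log2 fold changes 1.80) and mitochondrial genes (13 of 13, median 2.03) had positive estimates, where an estimate is the cisplatin difference with antibiotics minus that with water. Proliferation genes (31 of 32, median -1.10) and immediate early genes (16 of 16, median -1.67) had negative ones. Camera with a preset correlation called 14 lists, with an adjusted p of 2.73e-13 for adipocytes, and all 14 were lost at adjusted p = 0.572 to 0.733 with an estimated correlation. Only 2 of the 14, the adipocyte and mitochondrial lists, kept call and direction without each single library. The immediate early median was 0.26 without antibiotics and placebo library 2, and the proliferation median 0.06 without library 1. That library 1 was rich in granulosa, theca and oocyte markers. In edgeR 0 adipocyte, mitochondrial, proliferation or immediate early genes passed adjusted over the list alone or over all genes; DESeq2 called 0 of them. EdgeR called 0 genes, with 969 at an unadjusted p under 0.05 (357 to 1725 without 1 library); limma voom called 0 and DESeq2 31 (2 higher, 29 lower). Lmo4 (0.96 ± 0.24, SE) and Pfkfb3 (2.62 ± 0.68) were again among the 10 genes with the smallest p, each with an edgeR adjusted p of 0.842, beside Cdhr5, Scand1, Gm4129, Gm47766, A2ml1, 9530052C20Rik, Il24 and the vitamin transporter Slc5a6 (1.58 ± 0.44).

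The 2 estimates of each effect, which share no library, agreed little. Across the 19149 genes, which are not independent replicates, the cisplatin differences in water mice and in antibiotic mice had a Pearson correlation of 0.0616 and a Spearman correlation of 0.261, with 63.7% of genes of the same sign. The antibiotic differences in cisplatin mice and in placebo mice gave -0.0898 and 0.0512, with 53.9% of the same sign. The first Pearson value depended on single mice: it was 0.556 without antibiotics and placebo library 1 and -0.149 without antibiotics and placebo library 2. The second changed sign as well but stayed low. It ran from -0.239, without antibiotics and cisplatin library 3, to 0.192, without water and cisplatin library 3.

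Averaged over water and antibiotics, cisplatin tumors stood lower than placebo tumors in 15 of 16 adipocyte genes (median log2 fold change -0.88) and in 13 of 13 MHC class I genes (median -0.52). They stood higher in 30 of 32 proliferation genes (median 0.63) and 20 of 24 stem cell markers (median 0.52). These averages rested mostly on the water mice: cisplatin and placebo tumors had adipocyte levels of 8.13 and 10.08 log2 CPM with water but 9.73 and 9.86 with antibiotics, and proliferation levels of 4.38 and 2.97 but 3.63 and 3.48. Camera with a preset correlation called these and 10 other lists (14 in all; adipocyte adjusted p = 3.93e-09), all lost at adjusted p = 0.687 to 0.735 with an estimated correlation. Without each single library 5 of the 14 kept call and direction, and proliferation did not (median 0.32, adjusted p = 0.0688, without antibiotics and placebo library 2). In edgeR 1 adipocyte gene and 0 of the other 3 lists passed adjusted over the list alone, against 0 over all genes, where DESeq2 called 1 adipocyte gene lower. EdgeR called 0 genes, with 2187 at an unadjusted p under 0.05 (968, without antibiotics and placebo library 2, to 4360), limma voom 0 and DESeq2 152 (128 higher, 24 lower). Among the 10 genes with the smallest p were the milk protein genes Csn3 (placebo 86.6 ± 150 CPM with water and 16.5 ± 23.4 CPM with antibiotics, cisplatin 0.0631 ± 0.0728 and 0.0504 ± 0.101 CPM) and Lalba, the iodide transporter Slc5a5 and Tfap2b, each with an edgeR adjusted p of 0.428. The large SDs reflect 1 library per placebo group, with Csn3 at 260 CPM in water and placebo library 3 and 33.1 CPM in antibiotics and placebo library 1. Lmo4 (-0.55 ± 0.12, SE), Tpcn1 (-0.56 ± 0.13), Gm44969, Lmx1b, Gabrr2 and Irx1 were the remaining 6.

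Averaged over placebo and cisplatin, antibiotic tumors stood higher than water tumors in 30 of 30 ribosomal protein genes (median 0.51) and 15 of 16 adipocyte genes (median 0.49), and lower in 13 of 14 MHC class II genes (median -0.58), 19 of 20 fibroblast genes (median -0.45) and 15 of 16 immediate early genes (median -0.66). For 2 of these lists the average joins differences of opposite sign: antibiotic and water tumors had adipocyte levels of 9.73 and 8.13 log2 CPM in cisplatin mice but 9.86 and 10.08 in placebo mice, and immediate early levels of 5.66 and 7.39 but 5.24 and 5.14. Camera with a preset correlation called these and 7 other lists (12 in all; ribosomal adjusted p = 4.21e-08), all lost at adjusted p = 0.367 to 0.796 with an estimated correlation. Without each single library 4 of the 12 kept call and direction, and the immediate early list did not. In these 5 lists 0 genes passed in edgeR, adjusted over the list alone or over all genes, or in DESeq2. EdgeR called 0 genes, with 1119 at an unadjusted p under 0.05 (637 to 3778 without 1 library), limma voom 0 and DESeq2 71 (66 higher, 5 lower). The phospholipase gene Pla2g10 had no count in any water and placebo library and stood at 0.0496 ± 0.0354 CPM with water and cisplatin, 0.907 ± 0.726 with antibiotics and placebo and 1.26 ± 1.21 with antibiotics and cisplatin (edgeR adjusted p = 0.718). Lrrfip1, a nucleic acid binding protein, was the only one of the 10 genes with the smallest p to stand lower (-0.59 ± 0.13, SE), beside Vwa2, Bpifb5, Adgrd2-ps, Sall1, Plekhs1, Nkx2-3, Hoxb5os and Pax2. In the same libraries the urothelial markers were at 2.23 to 8.65 (mean log2 of CPM + 0.1) with antibiotics and at -0.72 to 3.93 with water, except for 8.78 in water and placebo library 1. The uterine markers were at 1.21 to 6.39 with antibiotics, -1.14 to -0.65 with water and placebo and -1.06 to 6.92 with water and cisplatin.

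**Figure D3:**
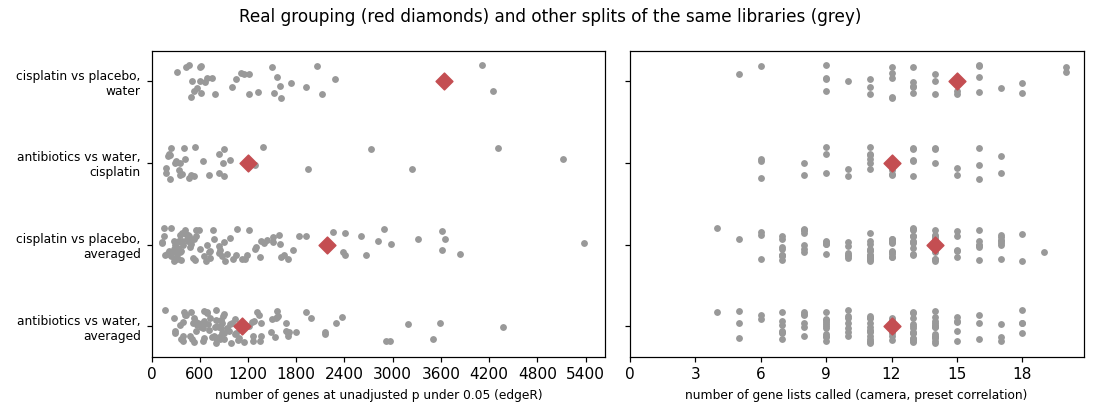
Number of genes at an unadjusted p under 0.05 in edgeR (left, horizontal axis) and of gene lists called by camera with a preset correlation (right) for 4 comparisons (rows), with the real groups as red diamonds and other splits of the same libraries as grey points. For cisplatin against placebo in water mice the real groups gave 3640 genes and 15 lists, and the other splits reached 4254 genes and 20 lists.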

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

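All tests of explanations below were chosen after the results they concern had been seen.

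In the 2 groups of 4 libraries a library far from the other 3 was sought in 96 comparisons of a measure within a group, which share the same 8 libraries. There were 7 such cases, where chance gives about 1 in 20, or 4.8. The p53 target level was 4.15 in water and cisplatin library 3 against 4.39 to 4.41 in the other 3, and the stem cell marker level was 3.48 in antibiotics and cisplatin library 1 against 4.02 to 4.12. The platinum transport and metallothionein level was 2.81 in antibiotics and cisplatin library 2 against 3.45 to 3.59. The skeletal muscle level was 5.50 in water and cisplatin library 4 against -1 to -0.746. Mki67 stood at 176 CPM in water and cisplatin library 3 against 54.4 to 72 CPM. Antibiotics and cisplatin library 2 stood apart in Vegfa (128 CPM against 21 to 37.6) and Aldh1a1 (1030 CPM against 182 to 319).

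Camera on the interaction with a preset correlation called 14 lists, all lost at adjusted p = 0.572 to 0.733 with an estimated correlation. The median difference of log2 fold changes was positive for adipocyte (1.80), mitochondrially encoded (2.03), skeletal muscle (8.33), erythroid (1.17), smooth muscle (1.23), MHC class I (0.505), fibroblast (0.401) and hypoxia (0.392) genes. It was negative for proliferation (-1.10), immediate early (-1.67), granulosa and theca (-5.76), NF-kB (-0.585), neutrophil (-1.16) and stem cell (-0.317) genes. Only the adipocyte and mitochondrial lists kept call and direction without each single library. Smooth muscle turned to -0.47 without water and placebo 1, immediate early genes to 0.26 and NF-kB to 0.36 without antibiotics and placebo 2, and proliferation to 0.06 without antibiotics and placebo 1. Granulosa and theca were at -0.24 and MHC class I at 0.12 without antibiotics and placebo 1, and neutrophil at -0.17 and erythroid at 0.62 without antibiotics and placebo 2. Skeletal muscle was at 1.77 without antibiotics and cisplatin library 1 and at -2.70 without the 2 muscle-rich libraries.

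The lower fat markers of cisplatin tumors in water mice may come from the drug, from a different share of fat tissue in the specimens, or from a batch marked by the letter in the library names. With the letter as a factor the adipocyte median was -1.70 against -1.83 without it, so the letter does not explain it. Pairs of adipocyte markers rose and fell together across the 13 libraries (median Spearman correlation 0.868), which could come from the share of fat tissue and would also hold for a loss of fat cells under cisplatin. With the adipocyte level as a covariate 297 genes were left at an unadjusted p under 0.05 of 3640; as the levels of the 2 groups do not overlap, this cannot tell fat from drug. The cause remains open.

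The higher fat markers of antibiotic tumors among cisplatin mice were weighed in the same way. The adipocyte median was 1.28 with the letter as a factor against 1.42 without it, so the letter does not explain it, and the correlation of 0.868 among markers could likewise come from the share of fat tissue. With the adipocyte level as a covariate, where the levels of the groups overlap, 6 of the 12 called lists had the opposite direction and 3 kept direction and call (immediate early, NF-kB and MHC class II), though all 12 calls of the main fit were lost at adjusted p = 0.512 or more with an estimated correlation. The covariate fit used the preset correlation only and adjusted for fat but no other tissue. The outcome of the adipocyte list in it was set in advance. Since the 4 water and cisplatin libraries enter both comparisons, their low fat content alone may produce both results. An effect of antibiotics on the share of fat is not excluded.

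The tissue markers that differ between libraries of 1 group could come from different host tissues in the specimens or from the letter batch; no biological explanation was tested. The letter separated 0 of 8 tissue lists without overlap. Only a full separation of libraries with and without the letter would have counted, so this test cannot exclude a partial shift. Nor can it tell the explanations apart if libraries with the letter also differed in host tissue. Within the skeletal muscle, smooth muscle and granulosa and theca lists the median correlations of marker pairs were 0.923, 0.599 and 0.815. The median of these 3 was 0.815, against -0.268 between the lists. Their genes were fixed in advance, but these 3 lists were picked for this test after the data had been seen. Markers of a list thus rose and fell together, as differing amounts of muscle and ovary would give, but the pick partly fixed this. Within the 5 lists chosen from the data (oviduct, oocyte, uterus, bladder, mammary gland) the median correlation was 0.777. The choice partly fixed that value, so for these the cause stays open too.

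Other splits of the same libraries show how far chance can go. For cisplatin in water mice, 3 of 35 splits, the real one among them, reached as many genes at an unadjusted p under 0.05 as the real groups (3640, highest other 4254), 12 of 35 as many lists (15, highest other 20), 3 of 35 as many DESeq2 calls (1399, highest other 2228) and 35 of 35 as many edgeR calls (0, highest other 1). For antibiotics in cisplatin mice the values were 8 of 35 (1205, highest other 5125), 19 of 35 (12, highest other 17), 18 of 35 (2, highest other 2809) and 35 of 35 (0, highest other 1). For 100 splits of the averaged effects they were 16 for genes (2187, highest other 5382) and 34 for lists (14, highest other 19) of cisplatin, and 37 (1119, highest other 4378) and 50 (12, highest other 18) of antibiotics. In the order given, the median of the other splits was 13, 12, 12 and 11 lists, against 15, 12, 14 and 12 with the real groups. For genes it was 1081.5, 512.5, 732 and 891, against 3640, 1205, 2187 and 1119. For DESeq2 calls, in the first 2, it was 75 and 1.5, against 1399 and 2. Other splits thus typically called nearly as many lists as the real groups. A count of 0 is reached by every split, so the edgeR calls cannot tell. Chance cannot be excluded for the other counts. For antibiotics in cisplatin mice other splits gave several times the real counts (5125 against 1205 genes, 2809 against 2 with DESeq2), which points to structure among the samples, such as the tissue content above.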

How the results depend on the processing

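Leaving out muscle-rich libraries or mitochondrially encoded genes, the adipocyte covariate and the exact permutation were added after the results had been seen. RLE factors, the filters, robust dispersion, limma voom, the letter factor, the adipocyte covariate, leaving out mitochondrially encoded genes and the replicate block left 0 genes called in every comparison. Where the setting differed, DESeq2 called 1399 genes for cisplatin in water mice, 2 for antibiotics in cisplatin mice, 77 for antibiotics in placebo mice, 31 for the interaction, 152 for cisplatin averaged and 71 for antibiotics averaged, all against 0 in edgeR. A fit of only the 2 groups called 1 gene for antibiotics in placebo mice (adjusted p = 0.0496). Leaving out libraries gave 0 to 102 genes for cisplatin in water mice. With an estimated correlation 0 lists were called in all 7 comparisons (smallest adjusted p = 0.643, 0.927, 0.512, 0.554, 0.572, 0.687 and 0.367, in the order of the methods), fry called 0 in all 7 for a common direction (smallest adjusted p = 0.179, 0.972, 0.498, 0.91, 0.76, 0.38 and 0.351) and 1 for mixed directions (integrated stress, cisplatin in water mice, adjusted p = 0.0397), and the exact permutation of library means called 0 in the 4 pairwise ones, where its smallest possible exact p before adjustment over 32 lists was 0.0571, 0.133, 0.0286 and 0.2, so that it could hardly call a list. With the adipocyte level as a covariate the called lists with the opposite direction were 9 of 15, 0 of 5, 6 of 12, 0 of 8, 6 of 14, 5 of 14 and 2 of 12, in the same order. In the first the levels of the groups do not overlap, so it cannot decide. Where the adipocyte list was among the called lists, its outcome was set in advance, as its own level was the covariate. Without mitochondrially encoded genes 14, 6, 11, 8, 12, 14 and 12 of the other 31 lists were called. Lists called for cisplatin in antibiotic mice, 5 in the main test, were 11 with the replicate block, 9 without the 2 muscle-rich libraries (antibiotics and cisplatin 1, water and placebo 3), and 3 to 12 without 1 library. Without 1 library the counts were 12 to 18 for cisplatin in water mice, 11 to 14 and 7 to 19 for antibiotics in cisplatin and placebo mice, 9 to 19 for the interaction, and 12 to 17 and 8 to 14 for the averages. Some lists changed direction. For MHC class I presentation with cisplatin in antibiotic mice the median log2 fold change was 0.056 without antibiotics and placebo 2 (-0.68 without antibiotics and placebo 1). For endothelium it was 0.16 (-0.59), and camera also turned without antibiotics and cisplatin 2 (-0.02). For smooth muscle and pericyte genes it was 0.42 for antibiotics in placebo mice (-1.81 without water and placebo 3) and -0.47 for the interaction (1.503 without water and cisplatin 4), both without water and placebo 1. For ovarian granulosa and theca genes without antibiotics and placebo 1 it was -0.77 for antibiotics in placebo mice (5.70 without antibiotics and placebo 2) and -0.73 for antibiotics averaged (2.603 without water and cisplatin 3). For immediate early genes in the interaction it was 0.26 without antibiotics and placebo 2 (-2.81 without water and placebo 2). For skeletal muscle it was -1.79 for antibiotics averaged without antibiotics and cisplatin 1 (3.49 without water and placebo 3), and -2.70 for the interaction without the 2 muscle-rich libraries. Medians of called lists that turned sign and lost their call without 1 library were also ribosomal 0.06 and smooth muscle 0.10 (cisplatin, antibiotic mice, without antibiotics and placebo 1), ribosomal 0.02 (cisplatin, water mice, without water and placebo 1), skeletal muscle -0.74 (antibiotics, cisplatin mice, without antibiotics and cisplatin 1) and 1.57 (cisplatin averaged, without water and placebo 3), smooth muscle 0.225 and immediate early 0.05 (antibiotics averaged, without water and placebo 1 and 2), and NF-kB 0.36 and proliferation 0.06 (interaction, without antibiotics and placebo 2 and 1). The cause was not tested. Replicate numbers did not pair libraries across groups: 16 pairs with the same number had a mean correlation of 0.058 and 46 others -0.02, and the block changed no other count by over 1.5 times.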

Other observations

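The relations below were chosen after the data had been seen. ID8 cells derive from ovarian surface epithelium, and the surface and mesothelial genes Wt1, Upk3b, Msln, Muc16 and Lrrn4 were taken as 1 level. Wt1, a transcription factor of that epithelium, stood at 187, 658 and 7.39 CPM with water and placebo, 577, 672, 376 and 538 CPM with water and cisplatin, 126 and 186 CPM with antibiotics and placebo, and 135, 978, 128 and 129 CPM with antibiotics and cisplatin. The surface markers are shared by tumor and host mesothelium, so their level is not a tumor share. Pax7, Pax3, Kcnd2 and Pcdhgc5 lay with Fos and Cxcl1 at an end of the second principal component (21.1% of the variance). Pax3 stood at 4.8, 14.9 and 0.256 CPM with water and placebo and 21.2, 16.5, 7.92 and 11.8 CPM with water and cisplatin. With antibiotics it stood at 1.6 and 3.04 CPM with placebo and 3.04, 32.4, 0.682 and 2.1 CPM with cisplatin. Like Wt1, it was not spread evenly over the groups compared, and its source was not tested.

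Across the 13 libraries the surface marker level had a Pearson correlation of -0.567 with the adipocyte level (permutation p = 0.0435, 0.0653 adjusted over 3 relations), -0.504 with the mitochondrial percentage (permutation p = 0.0812, 0.0812 adjusted) and 0.711 with the immediate early level (permutation p = 0.00451, 0.0135 adjusted). The Spearman correlations were -0.615, -0.648 and 0.637 (permutation p = 0.0283, 0.0194 and 0.0223, each 0.0283 adjusted). The permutations moved all 13 libraries freely between the groups, so these p-values do not separate the relations from group differences. With the group means removed the Pearson values were -0.409, -0.354 and 0.628, and no p was computed for them. Within the 6 libraries with the letter they were -0.67, -0.343 and 0.726. Within the 7 libraries without the letter they were -0.276, -0.399 and 0.567. Without the 2 libraries farthest from the middle (n = 11) they were -0.373, -0.391 and 0.748. The first value could come from shares of 2 tissues that replace each other, but the test cannot tell this from other causes, and no biological explanation was tested.

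Il2rg, the cytokine receptor gene disrupted in NSG mice, stood at 0.293 to 18.7 CPM, highest in water and cisplatin library 1 (18.7 CPM) and water and placebo library 2 (11.5 CPM).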
